A study of Drosophila melanogaster with 2 samples.

How the data were processed

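The data come from ChIP-seq of GFP-tagged kay in 0 to 24 hour whole embryos, with 2 biological replicates of 1 group, labelled 2 and 4. Per the labels, chromatin was sonicated on a Bioruptor to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody. The files used are the peak lists that the authors deposited, in narrowPeak format, for dm6 and dm3. Per the labels and the descriptions deposited with the samples, candidate lists were made from the alignments of 1 replicate, or of both pooled, and 1 control file, as input for the irreproducible discovery rate (IDR) procedure. The thresholded list was derived from the candidate lists of both replicates and of the pooled replicates. The peak caller, the aligner and their versions are not given in the sources used here. Alignments and signal tracks were not used here.

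Each peak carries a signal value, the unit of which the authors' peak caller set and whose scaling between libraries is not stated. The deposited signal was therefore used to rank and describe peaks within a list. Between the replicates' lists only a correlation of the ranks of the signals is reported. The deposited −log10 q value was at a single value (3.91) in all 3860 dm6 IDR peaks and was not used for ranking. The lists give no read counts, so the depth per sample is unknown, and nothing beyond counts of peaks sets the precision. All 3860 IDR peaks are among the 30000 pooled candidates and are exactly its 3860 strongest by signal. Of the 30000, 24854 overlap no IDR peak and served as the comparison set, since they could have become IDR peaks. The deposited names of the candidate lists call them peaks and background, so this set may hold background as well as weak peaks. Some IDR peaks overlap each other; they form 3575 clusters.

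Coordinates are 1-based in dm6. The genome sequence was the Release 6 assembly, whose arm lengths match the dm6 lists, and gene models were the 13945 protein-coding genes with 19607 TSSs on 6 arms in Ensembl release 115. Summits were placed by the nearest TSS (promoter: within 500 bp), and otherwise as 5' UTR, coding exon, 3' UTR, intron or intergenic, in that order. Motifs were searched on both strands within 50 bp of the summit. A gene was counted as bound when an IDR summit lay within 1 kb of one of its TSSs, with genes having a pooled candidate there as background. Names for older symbols were taken from the RefSeq table (stit as Cad96Ca, h as hry), and 2 list members (dp, dys) were not matched. No dm3 sequence was used, so dm3 entered counts and overlaps only.

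Shares were compared by Fisher's exact test, two-sided, with odds ratios and their 95% Woolf intervals (0.5 added to each cell where a cell was 0). Overlap of the replicates was tested by 1000 circular shifts within arms, and signals across peaks by 10000 permutations. Families of tests (11 other motifs, 17 gene lists, 5 location classes away from promoters) were adjusted by Benjamini-Hochberg. No comparison uses replicates as a measure of spread: with 2 libraries of 1 group, p values compare sets of regions in these libraries. No paired analysis was possible because there was 1 group.

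The tests, the motifs, the alternatives and the gene lists were fixed before the data were examined. The lists were JNK pathway, dorsal closure, AP-1 and JNK targets, epidermal wound response, bZIP factors, septate junction, trachea, muscle, nervous system, hemocyte and fat body, gut, segmentation, Hox, EGFR signalling, Hippo signalling, ribosomal proteins and chemoreceptors. Genes were named by a rule also fixed then: the nearest gene to each of the 15 strongest IDR peaks, kay and Jra, and up to 4 members per list with the strongest IDR peak within 1 kb of a TSS (2 for ribosomal proteins and chemoreceptors). List members without an IDR peak could be named with their best candidate. Other members of these lists and the locus of puc were named after their values were seen. Alternatives covered the overlap rule (reciprocal overlap of 50%, summits within 100 bp), the TSS and motif windows, the motif TGANTCA, the strongest 1930 peaks, each replicate alone, flanking windows, shifted peaks or GC-matched candidates as background (bins of 5 percentage points), gene assignment and dm3. Added after the data were seen were 1 peak per cluster of overlapping peaks, promoter or distal summits alone, dm3 for the replicate overlap, and the comparison of location classes among distal summits.

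The code was tested on simulated data. For the replicate overlap, regions of replicate 4 kept at a share of 59.4% and otherwise moved gave an overlap of 60.3% of 3860. For the AP-1 motif share, all 255 of 3860 candidate windows with a planted or own site were found, and 0 of 11 other motifs passed. For the AP-1 and JNK targets list (16 genes), 200 simulations at each planted odds ratio called the list in 24.0% at an odds ratio of 3, in 62.0% at 6 and in 94.5% at 12. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.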

Results

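The binding of kay, the single fly Fos protein and one partner of the AP-1 transcription factor, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole *Drosophila melanogaster* embryos of mixed sex, 0 to 24 hours old. The embryos came from a transgenic line that carries kay with GFP fused to its C-terminus, and an anti-GFP antibody pulled down the tagged protein. All samples form 1 group, with 2 biological replicates that the labels number 2 and 4, so no condition was compared with another. For each replicate, and for both pooled, the deposited lists hold 30000 candidate regions in the dm6 build, which their names call peaks and background. A further list holds the 3860 regions that the authors kept after the irreproducible discovery rate procedure, which compares replicates (here called IDR peaks). These lists carry no read counts, so the depth of each library is unknown, and the intervals given with shares are exact binomial (Clopper-Pearson) 95% intervals that cover counting error only. The signal of a peak is the value the authors' peak caller gave it, and it was used to rank and describe peaks within a list.

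The first question was where the tagged kay protein was bound most strongly. The strongest of the 3860 IDR peaks, with a signal of 2530.6, lay at 2L 6610626 to 6611179 (dm6), with its summit between genes and 75 bp from a transcription start site (TSS) of CG11050. A further peak in an intron of the same gene ranked 8. The 3rd strongest peak (signal 1830.6, 2L 480528 to 481334) lay in an intron of ush, a GATA cofactor gene of the dorsal closure list, and its nearest TSS, 1368 bp away, was that of cbt, a zinc finger factor; it ranked 2 in replicate 2 and 5 in replicate 4. The rest of the strongest 15 peaks lay nearest to l(2)k09913, CG14100, Rac2 (a Rac GTPase), Galphai (a G protein subunit), Ugalt (a UDP-galactose transporter), Zw (glucose-6-phosphate dehydrogenase), Khc (kinesin heavy chain), Tbca (a tubulin-binding cofactor), HmgZ, mRpL41, Sox14 and Sirt1. Of these 15 peaks, 9 had their summit within 500 bp of a TSS, 5 in an intron farther away and 1 between genes, and all 15 ranked among the strongest 30 candidates of each replicate.

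The genes of AP-1 itself were among the strongly bound ones. The strongest peak at kay ranked 24 of 3860 (signal 948.6, 3R 29782405 to 29782831) and sat in a 5' UTR, 41 bp from an internal TSS of the gene, and contained no AP-1 site. A second kay peak (signal 853.1, 3R 29771569 to 29772003) lay in an intron, with its summit 16 bp from the AP-1 site at 29771750 to 29771756, in the sequence CCGATGAGTCATCGC. From 3 kb before to 3 kb after kay there were 10 IDR peaks in 8 separate clusters, among 26 candidates. Of the 10 peaks, 5 contained an AP-1 site, with 3 different sites in all. Those at ranks 165 and 1738 lay in a kay intron but nearest to a TSS of another gene, fig. From 3 kb before to 3 kb after puc, which encodes the phosphatase that switches off JNK, there were 9 IDR peaks in 7 clusters among 25 candidates. The peak at rank 1860 lay between genes, 330 bp from a TSS of CG7878. Those at ranks 72 and 3486 lay in a puc intron but also nearest to a TSS of CG7878. Of the 9 peaks, 7 contained an AP-1 site, with 6 different sites in all, as overlapping peaks shared some. The strongest puc peak ranked 47 (signal 765.0, 3R 8105747 to 8106391). Its summit fell in a coding exon 482 bp from a TSS, and an AP-1 site lay 12 bp from the summit (AGCGTGAGTCATATA, 8105987 to 8106001). Jra, which encodes the Jun partner of kay, ranked 53 through a peak in its 5' UTR (signal 725.9, 2R 10096720 to 10097297) that held 2 AP-1 sites, the nearer one 120 bp from the summit. In the lists of single replicates these peaks ranked 27 and 23 (kay), 46 and 36 (puc) and 35 and 79 (Jra) in replicates 2 and 4.

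**Figure D1:**
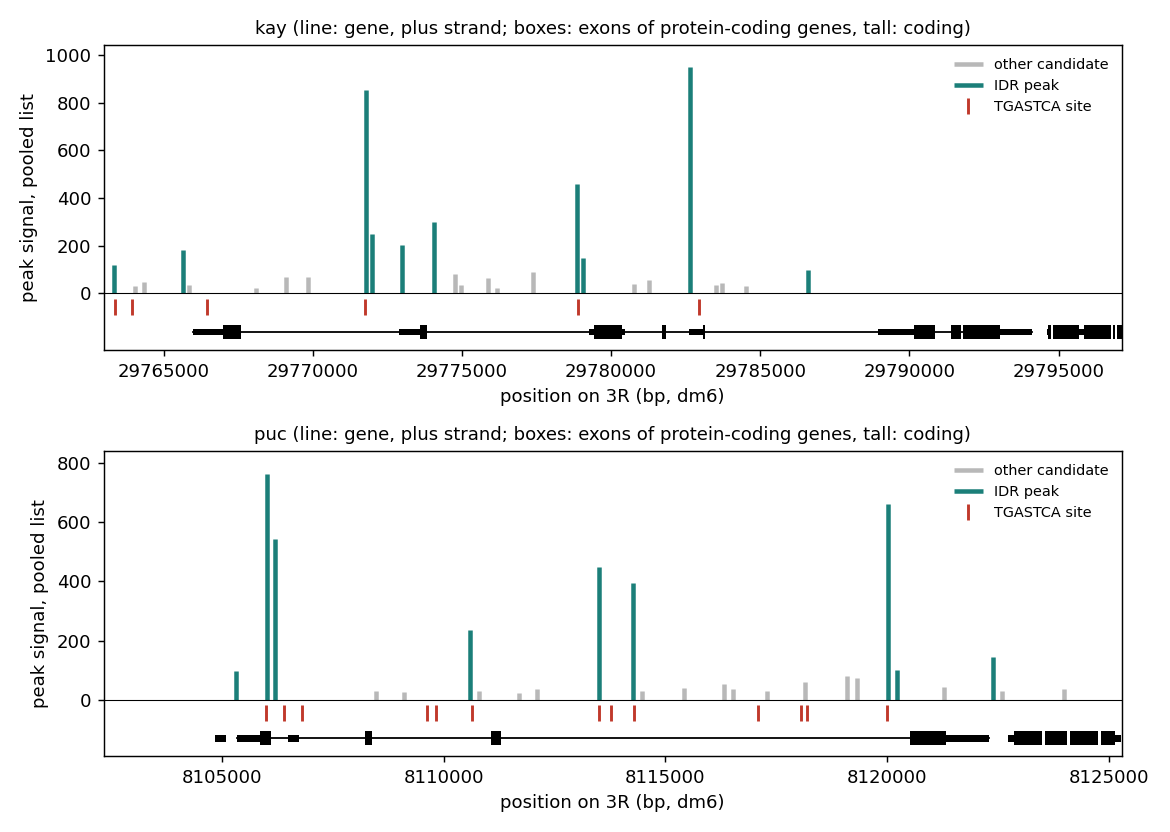
Peak signal of the pooled candidates (vertical lines at the summits; dark: IDR peaks, grey: others) against position on 3R in dm6 at kay and puc, from 3 kb before to 3 kb after each gene. Red ticks mark TGASTCA sites and black boxes the exons of protein-coding genes; the strongest lines stand at 948.6 in kay and 765.0 in puc.

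The replicates shared most of their strong regions. Of the 3860 strongest candidates of replicate 2, 3087 (80.0%) overlapped one of the 3860 strongest of replicate 4 by at least 1 bp, against a mean of 2.34% and at most 3.32% after the second set was shifted along each chromosome arm 1000 times (permutation test, one-sided, p = 0.001, the smallest these shifts can give). The IDR peaks come from a procedure that compares these replicates, and they are the 3860 strongest pooled candidates. Both facts bear on the values that follow. Of the IDR peaks, 3427 (88.8%) overlapped the strongest 3860 of replicate 2 and 3385 (87.7%) those of replicate 4. Across the 3854 IDR peaks with a candidate in both replicates, Spearman's rho between the ranks of their signals in the 2 lists was 0.719 (permutation test, one-sided, p = 0.0001, the smallest possible). Peaks are not independent replicates, and this p describes these 2 libraries only.

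The next question was which parts of the genome the IDR peaks occupied. IDR peaks were concentrated at promoters: 2112 of 3860 summits (54.7%, interval 53.1 to 56.3%) lay within 500 bp of a protein-coding TSS, against 6401 of 24854 pooled candidates that overlapped no IDR peak (25.8%). The odds ratio was 3.48 (95% interval 3.25 to 3.73, Fisher's exact test, two-sided, p = 2.9e-270). Against IDR peaks shifted at random along the arms, of which 11.4% reached a promoter, the odds ratio was 9.37. Because a higher promoter share lowers every other share, the remaining classes were compared among the summits away from promoters, 1748 of IDR peaks and 18453 of the other candidates, in a test chosen after the data were seen. There, coding exons were depleted, with 9 IDR summits (0.515%) against 6.48% of candidates (odds ratio 0.0747, adjusted exact p = 1.8e-35). The 3' UTRs were depleted as well (1.49% against 7.15%, odds ratio 0.196, adjusted exact p = 4.8e-26; Fisher's exact tests, two-sided, Benjamini-Hochberg over 5 classes). Introns made up the larger part in both sets (69.4% against 59.3%), a difference that cannot be separated from the loss of exonic summits. Intergenic sequence (27.3% against 25.7%, adjusted exact p = 0.17) and 5' UTRs (1.32% against 1.41%, adjusted exact p = 0.83) did not differ. The median distance to a TSS was 356.5 bp for IDR peaks and 1767.5 bp for the other candidates. Because the IDR list is exactly the 3860 strongest of the pooled candidates, these tests compare strong with weak regions of the same libraries. The weak regions may include background.

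**Figure D2:**
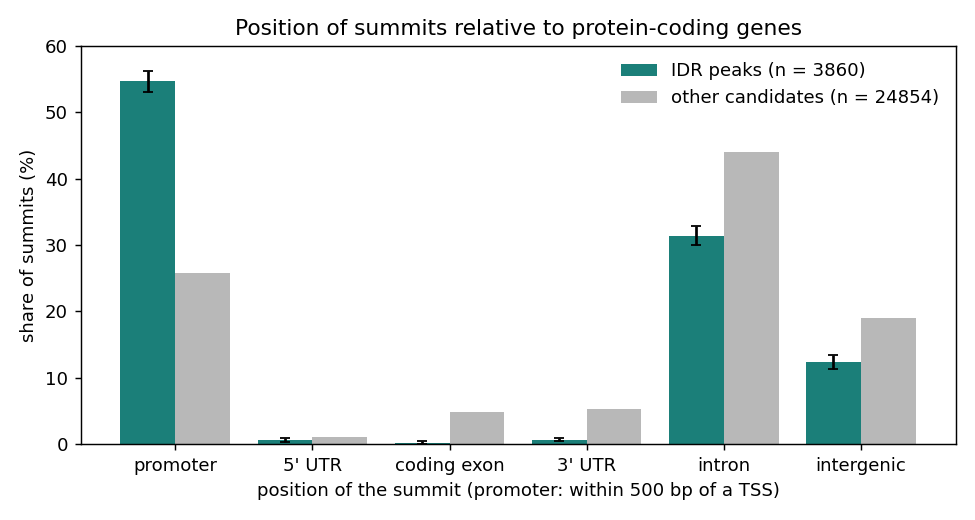
Share of summits (%) by position for 3860 IDR peaks (dark bars, with 95% Clopper-Pearson intervals) and 24854 other pooled candidates (grey bars). Promoter summits made up 54.7% of IDR peaks and 25.8% of the others.

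Fos and Jun dimers recognise the sequence TGASTCA, where S is C or G, and this AP-1 site was enriched at kay peaks. A site lay within 50 bp of the summit in 184 of 3860 IDR peaks (4.77%) and in 536 of 24854 other candidates (2.16%), an odds ratio of 2.27 (95% interval 1.91 to 2.69, Fisher's exact test, two-sided, p = 1.6e-18). Windows 500 bp to either side of the same summits had a site in 1.08%, and against these the odds ratio was 4.61. The sites gathered at the summit: per 20 bp bin and 100 summits there were 1.15 sites within 20 bp of IDR summits and 0.202 beyond 300 bp, a ratio of 5.71, while the other candidates had a ratio of 2.40. Named examples were Ets21C, an ETS factor, with a site 16 bp from its summit (CGTATGAGTCACCCG, 2L 552734 to 552748, summit in a 5' UTR), and chic, which encodes profilin, with one 20 bp away (GCCGTGAGTCACCCG, 2L 5980240 to 5980254, summit also in a 5' UTR). Rac2 had a site 3 bp from the summit (ACAGTGAGTCATTCG, 3L 7435399 to 7435413, summit in an intron of CG42458) and Tbca one 1 bp away (GCTCTGACTCACTGG, 3R 31743445 to 31743459, summit between genes). IDR peaks at promoters carried a site less often than those farther away, 82 of 2112 (3.88%) against 102 of 1748 (5.84%), an odds ratio of 0.652 (95% interval 0.484 to 0.878, Fisher's exact test, two-sided, p = 0.0049). The other candidates showed the same tendency (1.59% at promoters against 2.35% farther away), so it was not particular to IDR peaks. The enrichment of IDR peaks over candidates was alike in both places, with odds ratios of 2.49 and 2.57. Within IDR peaks, at their full width, 452 (11.7%) contained a site, as did 8 of the strongest 15. The strong peaks of Mmp1 (rank 89), Mkk4 (rank 91) and Atf3 (rank 125) contained none.

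**Figure D3:**
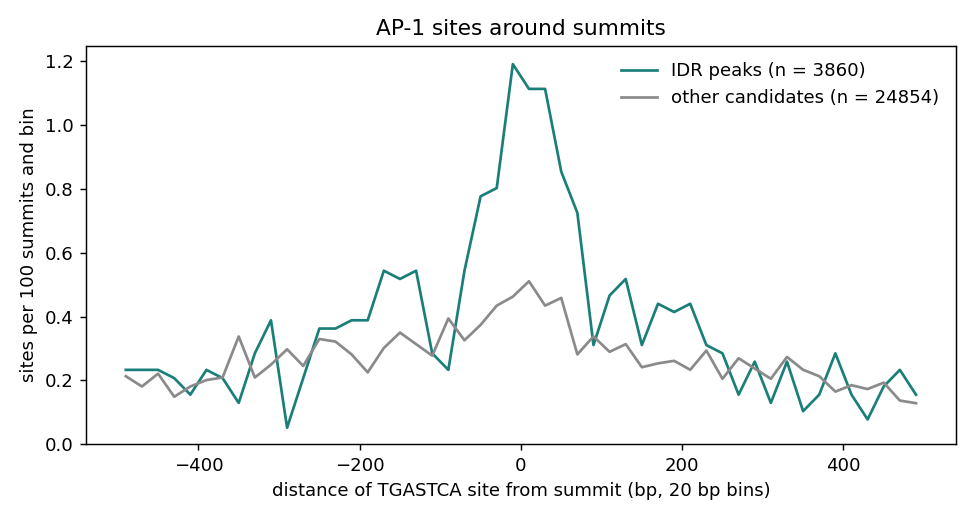
Number of TGASTCA sites per 100 summits in 20 bp bins (y axis) against distance from the summit in bp (x axis) for 3860 IDR peaks and 24854 other pooled candidates. Sites near IDR summits reached 1.19 per 100 summits in the highest bin, against 0.511 near the others.

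The share of peaks with an AP-1 site was higher in the strongest IDR peaks, though this rested on few sites. The strongest 772 peaks included the strongest peak of each of kay, puc and Jra. Of those only the puc peak had a site within 50 bp of the summit. Among the strongest 772, 50 (6.48%, interval 4.84 to 8.45%) had a site within that distance, against 26 (3.37%, interval 2.21 to 4.90%) in the weakest 772. The odds ratio was 1.99 (95% interval 1.22 to 3.23, Fisher's exact test, two-sided, p = 0.0065). The 3 groups of 772 in between had 4.79%, 4.66% and 4.53%. The difference was not significant in replicate 2 alone (odds ratio 1.27, exact p = 0.32), between the stronger and weaker 1930 peaks (1.32, p = 0.082) or away from promoters (1.84, p = 0.098). It was significant in replicate 4 alone (1.82, exact p = 0.013), at promoters (2.92, p = 0.0042), within 100 bp (1.82, p = 0.0028) and with 1 peak per overlapping cluster (2.22, p = 0.0028). The promoter share went from 61.4% in the strongest 772 peaks to 48.1% in the weakest, a trend that was not tested.

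Of 11 other motifs fixed in advance, 1 differed between IDR peaks and the other candidates. The DNA replication-related element TATCGATA (DRE), the site of the promoter factor DREF, was found in 69 IDR peaks (1.79%) against 0.95% of candidates, an odds ratio of 1.90 (adjusted exact p = 1.5e-04, Fisher's exact test, two-sided, Benjamini-Hochberg over 11 motifs). In replicate 4 alone it was found in 96 peaks (2.49% against 0.777%), and the odds ratio was 3.26 (adjusted exact p = 5.4e-17). The DRE odds ratio was 2.05 in replicate 2 alone (adjusted exact p = 1.1e-05) and 1.74 with GC-matched candidates (adjusted exact p = 0.037). The GAGA repeat GAGAGAG occurred in 2.15% against 1.64% and did not pass (adjusted exact p = 0.15). It passed with candidates matched on GC content (adjusted exact p = 0.014), in replicate 2 alone (0.0047) and within 100 bp (5.5e-08). It did not pass in replicate 4 alone (odds ratio 1.27, adjusted exact p = 0.20). With 1 peak per overlapping cluster GAGA occurred in 1.87% against 1.64% (odds ratio 1.14, adjusted exact p = 0.88). The cAMP response element TGACGTCA was rare (0.337% against 0.282%, adjusted exact p = 0.64) and passed only within 100 bp (0.017). The sites of Zelda, Grainyhead, GATA factors, ETS factors, E-box proteins, TEAD factors, homeodomain proteins and C/EBP had adjusted exact p values from 0.64 to 0.80. IDR summits lay at promoters more often than those of the other candidates (54.7% against 25.8%). These 11 motifs were not compared within promoter or distal summits, so the DRE and GAGA results cannot be separated from that difference in position.

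The genes whose promoters were bound were then compared across 17 gene lists. An IDR summit lay within 1 kb of a TSS for 2977 of the 8391 genes that had any candidate there (35.5%). JNK pathway promoters were bound in 9 of 17 cases (odds ratio 2.05, adjusted exact p = 0.33): beside kay, puc and Jra these included Mkk4, which encodes a kinase that activates JNK (rank 91, signal 600.3, nearer to the TSS of SLIRP2), bsk, which encodes JNK itself (rank 2522, signal 122.3), and the TNF receptor gene grnd (rank 2621, nearer to the TSS of CG10283). Of the AP-1 and JNK targets 9 of 16 were bound (odds ratio 2.34, adjusted exact p = 0.32; 3.55 and 0.20 in replicate 4 alone), among them Ets21C (rank 69, signal 684.1), the matrix metalloproteinase gene Mmp1 (rank 89, signal 607.0; 134 and 61 in replicates 2 and 4), Atf3 (rank 125, signal 519.1) and jar, which encodes myosin VI (rank 331). The targets upd3 (rank 10349), rpr (rank 19272; 12680 and 11946 in replicates 2 and 4) and dpp (rank 15286; none in replicate 2 and 9867 in replicate 4) had only weak candidates. Dorsal closure genes were bound in 11 of 23 cases (adjusted exact p = 0.47), led by the myosin light chain gene sqh (rank 45, signal 777.2), chic (rank 73, signal 648.9) and Rho1 (rank 251, signal 371.8). For bZIP factors the count was 10 of 16 (odds ratio 3.04, p = 0.034, adjusted exact p = 0.26), with Irbp18 at rank 300 through a peak nearer to the TSS of APP-BP1, and for septate junction genes 9 of 14 (odds ratio 3.28, p = 0.045, adjusted exact p = 0.26), with Tsf2 at rank 1148. These p values are from Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the 17 lists.

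Among signalling lists, EGFR genes were bound in 7 of 11 cases (adjusted exact p = 0.26), with the ligand gene spi at rank 366 and the ETS repressor gene aop at rank 669 (1112 and 379 in replicates 2 and 4). Hippo pathway genes were bound in 8 of 13 cases (adjusted exact p = 0.26), with CycE at rank 1404 (1054 and 2861 in replicates 2 and 4) and ds at rank 1432. Epidermal wound response genes had 3 of 14 (odds ratio 0.495, adjusted exact p = 0.53), with Src64B at rank 357 (294 and 549 in replicates 2 and 4), Ddc at rank 2737 and Cad96Ca at rank 3466. In replicate 4 alone 5 of 14 wound response genes were bound, with an odds ratio of 0.984. Tissue and patterning lists held few genes with a candidate, and none passed the test (adjusted exact p from 0.47 to 1). Muscle had 6 of 12 (odds ratio 1.82, tin at rank 689) and gut 3 of 8 (1.09, lab at rank 902). The odds ratios of the others were below 1. Nervous system had 2 of 8 (0.606, elav at rank 200, its summit in an intron of the neighbouring gene arg). Segmentation had 2 of 8 (0.606, hry at rank 435, bcd at rank 1631) and trachea 1 of 7 (0.303, trh at rank 2561). Hox had 1 of 8 (0.260, lab), and hemocyte and fat body 0 of 4 (0.202). In replicates 2 and 4, hry ranked 321 and 879, lab 1402 and 655, and trh 1559 and 3328. Ribosomal protein genes had 38 of 89 (RpS27 at rank 286, RpL34b at rank 311, adjusted exact p = 0.38). Only the chemoreceptor genes passed the test, and they were bound less often, in 2 of 25 cases (8% against 35.6%, odds ratio 0.158, 95% interval 0.0371 to 0.669, adjusted exact p = 0.047, Fisher's exact test, two-sided). These were Or88a (rank 919) and Gr32a (rank 3203), whose peaks lay nearer to the TSS of CG12402 and Idua. In replicate 2 alone the odds ratio was 0.0749 (adjusted exact p = 0.0050). The call was lost in replicate 4 alone (odds ratio 0.272, adjusted exact p = 0.13) and with the strongest 1930 peaks (0.161, adjusted exact p = 0.19). Short lists that did not pass may still differ. In the simulations of a 16-gene list, a planted odds ratio of 3 was called in only 24.0%.

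The list results depended on how peaks were assigned to genes and on the background. When a gene was credited with any summit in its body or 1 kb around it, 4 lists passed as higher: dorsal closure (21 of 24, adjusted exact p = 3.6e-05), septate junction (12 of 15, 0.010), EGFR (10 of 11, 0.0042) and Hippo (10 of 13, 0.031). By nearest TSS these 4 passed along with AP-1 and JNK targets (14 of 18, adjusted exact p = 7.5e-04) and bZIP factors (11 of 16, 0.017). Against all 13945 protein-coding genes, 8 lists passed as higher, the JNK pathway (9 of 17, adjusted exact p = 0.010) and ribosomal proteins (38 of 92, 1.4e-04) being added to these 6. Chemoreceptors passed as lower in all 3 settings (adjusted exact p of 0.0034, 0.0011 and 5.3e-15; Fisher's exact tests, two-sided). By gene body and by nearest TSS, genes that are long or far from others offer more room for summits. Lists and background were not matched on length or spacing, so the results of these settings cannot be separated from them. Against all protein-coding genes, the bound counts were those of the main test, and genes without any candidate joined the background. For the JNK pathway list, the share of other genes bound thereby went from 35.4% to 21.3%. Results of that setting cannot be separated from whether a gene had a candidate at all.

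**Figure D4:**
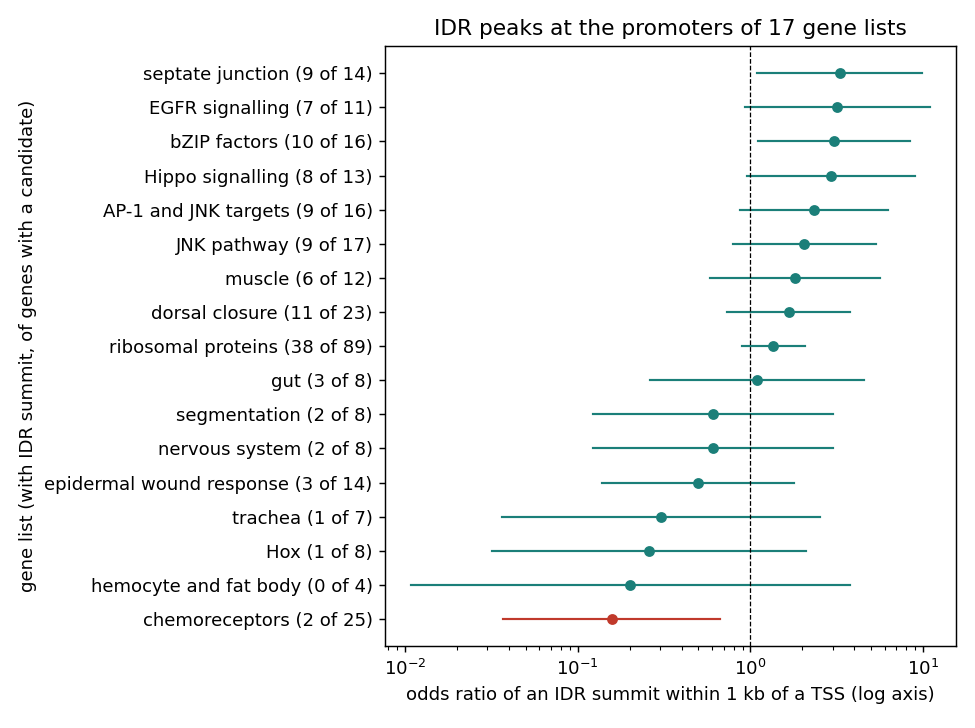
Odds ratio (log axis) of an IDR summit within 1 kb of a TSS for 17 gene lists against all other genes with a candidate, with 95% intervals; counts stand beside each name. Chemoreceptors, in red, were the only list past an adjusted p of 0.05, with an odds ratio of 0.158.

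The chromosomal and assembly-level counts were compared last. On the X chromosome, where sqh, Atf3, elav, Zw and Ugalt lie, there were 619 IDR peaks (16.0%), against 16.96% of the other candidates, an odds ratio of 0.935 (95% interval 0.853 to 1.03, Fisher's exact test, two-sided, p = 0.16) that did not differ from 1. It was 0.903 in replicate 2 alone (exact p = 0.033) and 1.08 in replicate 4 alone (p = 0.081). Processing of the same libraries against the older dm3 build gave 3891 IDR peaks covering 1603119 bp in sum, against 3860 covering 1601662 bp in dm6. Counts per arm in dm6 and dm3 were 728 and 732 on 2L, 720 and 734 on 2R, 812 and 817 on 3L, 969 and 973 on 3R, 12 and 12 on chromosome 4, and 619 and 623 on X.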

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

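A signal appeared in data outside the main measurement. In dm3, 66 of the 30000 pooled candidates lay on sequences outside the 6 chromosome arms, while the dm6 candidates had 0 there, and 0 of the dm3 IDR peaks were on such sequences. The lists of replicates 2 and 4 had 58 and 124 such candidates in dm3. No explanation for these was tested.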

How the results depend on the processing

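The replicate overlap (68.0 to 80.3%), the promoter odds ratio (2.98 to 9.37) and the AP-1 odds ratio (1.89 to 4.61) kept their direction and stayed past the threshold in every alternative run. The cluster, promoter-only, distal-only and dm3 overlap settings were chosen after the data were seen. The odds ratio of AP-1 sites between strong and weak peaks was 1.32 between the stronger and weaker 1930 and 1.84 in distal peaks, both without significance, and 1.27 to 1.82 in single replicates. The X odds ratio was 0.903 to 1.08 in single replicates, crossing 1, and passed in replicate 2 only. Other motifs that passed numbered 3 within 100 bp, 2 with GC-matched candidates and 1 to 2 in single replicates, against 1. Gene lists that passed numbered 5 by gene body, 7 by nearest TSS and 9 against all protein-coding genes, against 1. With the strongest 1930 peaks 0 passed by Fisher's exact test (4 at unadjusted p under 0.05), and in single replicates 0 to 1 (6 at unadjusted p under 0.05 in replicate 2 alone and 3 in replicate 4 alone, against 3). The cause was not tested in any of these. Odds ratios of other motifs and lists crossed 1, without passing the test, as follows. By cluster, CRE had 0.993; within 100 bp, Grainyhead had 0.786 and TEAD 0.998; with GC matching, E-box had 1.07. In single replicates Zelda had 0.919 to 1.18, Grainyhead 0.398 to 0.40, the nervous system list 0.295 to 1.25 and the gut list 0.886 to 0.940. By gene body, the wound response list had 1.5, Hox 1.5 and gut 0.897; by nearest TSS, wound response had 2.12 and Hox 3.54; against all genes, wound response had 1.00; with the strongest 1930 peaks, segmentation had 1.29. Of the named genes, 3 left the strongest 3860 of a single replicate (Gr32a at 3912 and Cad96Ca at 3980 in replicate 2, scrt at 7442 in replicate 4). The lists hold no depth, so none of these could be related to it.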

Other observations

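The tests of 7-base words, of extra copies of kay and of list strength were chosen only after the result was seen. Several genes had many separate kay peaks within or near them. These genes were named after their values were seen. Counting clusters of overlapping IDR peaks within a gene and 1 kb around it, 49 of 3780 genes with any cluster had 5 or more. The highest counts were at CG1677 (14 clusters in a gene of 124.7 kb), tara (11 in 34.7 kb), ush (10 in 64.3 kb), sbb (10 in 79.1 kb), CHES-1-like (9 in 27.0 kb, encoding a forkhead factor), Raf (9 in 48.4 kb, the kinase downstream of Ras) and shn (9 in 58.3 kb, a zinc finger factor of the Dpp pathway). Eip75B and Hr4, both nuclear receptor genes, had 8 each in 113.7 kb and 66.0 kb. By this count puc (16.96 kb) and kay (28.1 kb) had 7 each, a number reached by 20 genes, of which 4 were as short as kay or shorter. Longer genes offer more room for peaks, and the counts were not tested against length. Clusters counted at a gene can also lie at promoters of other genes within or beside it. The strongest peak counted at CG1677 (signal 424.8) lay within 1 kb of a TSS of CBP.

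Sequence words of 7 bases were then counted without any motif in mind. Against GC-matched candidates, 14 of 8192 words were more frequent in IDR peaks and 6 less frequent (Fisher's exact test, two-sided, Benjamini-Hochberg over all words). TGACTCA, with its complement TGAGTCA the AP-1 site, ranked first (4.77% against 1.81%, odds ratio 2.71, adjusted exact p = 1.9e-09). Of the other words, AGCACTG (2.90% against 1.06%, odds ratio 2.78, adjusted exact p = 1.6e-05) and ACTATCG (2.75% against 1.01%, odds ratio 2.77, adjusted exact p = 3.7e-05) are not parts of the AP-1 site. Against all candidates 267 words were higher, 57 of them made of A and T alone, and the same 3 words led those with a G or C. AGCACTG and ACTATCG were not compared within promoter or distal summits. Their results cannot be separated from the higher promoter share of IDR peaks.

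Most IDR peaks had no AP-1 site near the summit and over 50% lay at promoters. If promoter signal without any AP-1 preference were the whole source, promoter IDR peaks should not exceed promoter candidates in AP-1 sites. Yet their odds ratio was 2.49 (95% interval 1.86 to 3.35, Fisher's exact test, two-sided, p = 3.8e-09), in a setting chosen after the data were seen. This argues against it as the whole source only. Just 82 of 2112 promoter IDR peaks (3.88%) had a site, and the test does not bear on the others. Sites with 1 mismatch may account for a small part. Among windows without an exact site, 695 of 3675 IDR peaks (18.9%) had one against 16.0% of GC-matched candidates (odds ratio 1.22, 95% interval 1.08 to 1.38, Fisher's exact test, two-sided, p = 0.0011). These windows were not compared within promoter or distal summits, so this excess cannot be separated from the higher promoter share of IDR peaks. Binding through other proteins and signal at open promoters in general stay open, and the control track was not used here. No biological explanation that needs a contrast between groups was tested, since the design has 1 group.

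Chromosome 4 had 12 IDR peaks among 498 regions, counting IDR peaks and the candidates that overlap none (2.41%, against 13.6% on the other arms, odds ratio 0.156, Fisher's exact test, two-sided, p = 6.8e-18), although its 503 pooled candidates were the densest of the 6 arms (373.1 per Mb). Fewer promoters among its candidates (22.1% against 29.8%) could lower the share, but among promoter summits alone the odds ratio was still 0.173 (95% interval 0.0756 to 0.393, Fisher's exact test, two-sided, p = 1.5e-07). Its lower GC content (35.1% against 39.1%) could do so too, but within GC bins the Mantel-Haenszel odds ratio was 0.141 (95% interval 0.0797 to 0.250). Both tests argue against these as the whole cause. Mappability and repeats on this largely heterochromatic arm were not tested and stay open.

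The strong peaks at kay could reflect extra copies of the locus in the tagged line. The labels call the line transgenic and name an insertion targeting kay, without saying whether the tagged gene is an additional copy. The strongest kay peak was 14.1 times the median candidate of the same locus (14.8 at puc), but an added copy would lift all regions of the locus alike and leave this ratio as it is, so it decides nothing and extra copies stay open. As a hypothesis, AP-1 and JNK targets may have stronger promoter candidates than other genes. Their median percentile of signal was 79.1 among genes with a candidate, but the permutation test (two-sided, p = 0.0073) gave an adjusted p of 0.0501 over 17 lists, short of the threshold. A high percentile was not particular to the list: EGFR signalling (median percentile 81.0) and ribosomal proteins (62.4) had the same adjusted p. Segmentation (14.9) and trachea (13.7) shared that adjusted p too, but with weaker candidates than other genes. The unadjusted permutation p values of these lists differed, from 0.0073 to 0.018, and the adjustment gave them 1 shared value. In the same permutation test only chemoreceptors passed, with a median percentile of 22.3 (adjusted p = 0.038).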
